A study of Mus musculus with 9 samples.

How the data were processed

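Bulk RNA sequencing of colonic epithelial cells from 9 mice was analysed: 3 naive mice, 3 syngeneic and 3 allogeneic transplant recipients, each a biological replicate per the labels. RNA was isolated with RNeasy columns, its quality read on a Bioanalyzer, and libraries made with standard Illumina protocols, per the labels. The submitters' processing notes name the aligner STAR, the test DESeq2 and the mouse genome build mm10 without versions or roles. The counting program, annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here.

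The deposited table holds raw counts per Ensembl gene for 32976 genes in 9 columns, as the authors made it, with no normalization: the values are whole numbers whose column totals differ. Columns were matched to samples by the animal numbers in the sample titles, and 0 columns were left unused. Gene symbols and positions came from GENCODE release M21 on GRCm38 (the mm10 assembly), which named 31980 identifiers; the other 996 hold 0.131% to 0.182% of the counts of a library. A RefSeq table named 0 more, and 6 symbols belong to more than 1 identifier. In 11120 genes no library held a count. Library totals ran from 19961346 to 30214449 counts. A count of 0 allows up to 3 counts, or 0.0993 to 0.15 per 1000000 counts, a limit that covers counting error only. Paralogous genes may share reads, and alleles of the BALB/c donors differ from the reference, so values of single paralogues in the class I, guanylate-binding protein, T cell specific GTPase and carboxylesterase families are less certain. H2-Ea, a class II gene transcribed in BALB/c but not in C57BL/6 mice, was on a list of 2 names that found no gene in the table and was not analysed here.

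Counts were normalized with TMM factors and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 14384 genes. All 9 libraries entered 1 group-means model with robust dispersion estimates and robust quasi-likelihood fits (common biological coefficient of variation 0.204, median prior degrees of freedom 3.77), so that the 3 groups share 1 spread per gene. Each of 3 contrasts was tested by the quasi-likelihood F test, and p values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM of genes are counts per 1000000 counts of a library's TMM effective size, given as mean ± SD of 3 libraries. Sums over markers, shares of counts and the 3-count limit use unscaled library totals. Principal components used log2 CPM with a prior count of 2. Intervals at 95% for sums in 1 library are exact Poisson limits and cover counting error only.

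The 37 gene lists hold 641 distinct symbols, a few of them on more than 1 list. They cover respiratory complexes I to V, mitochondrially encoded genes, the tricarboxylic acid cycle, glycolysis, fatty acid oxidation and ketogenesis, and cholesterol synthesis. Others cover MHC class I and II presentation, interferon responses, antimicrobial defence, cell death, p53 targets, cell cycle, stress responses and hypoxia. The rest cover immediate early genes, tight junctions, epithelial cell types and markers of other cells. Lists with at least 3 measured members (35 of them) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The sex-linked list (Xist alone was tested, and its value is given with the depths) and the H2-Ea list were not tested as sets. Member counts are given over all genes and adjusted over the list alone. Groups, comparisons, tests, lists and alternatives, and the rule for named genes were set before the data were examined. That rule takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with a mean of at least 10 CPM and no overlap between groups, leaving out unnamed, Gm-numbered and Rik symbols. It adds up to 4 called members of each list with the smallest p, or 1 or 2 members with the highest mean where none was called, the 4 complex II genes always, and the values of a named gene in other comparisons. Fer1l4 and the lone members that moved against their list (Sesn2, Acadl, Pfkl, Pfkm, Ang4 and Ms4a7) fall outside the rule and were named after their values were seen. Some genes that the rule takes are not reported here.

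The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, no filter on low counts, at least 10 CPM in 3 libraries, a fit of the 2 compared groups alone, the replicate number as a block, thresholds of 0.01 and of 1 on the log2 scale, and each library left out in turn. Leaving out the mitochondrially encoded genes was added after the data were seen. The low-count filter was run anew in each edgeR fit, so the genes tested and the measured members of a list could differ between alternatives.

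The pipeline was tested on simulated data with 200 changed genes. Mean levels were those of allogeneic and syngeneic, of syngeneic and naive, and of allogeneic and naive libraries in turn. The spread per gene was the same in each, from the fit of all 9 libraries, so no comparison's own spread was simulated. Of genes changed by 1 on the log2 scale edgeR recovered 49%, 53% and 48% in that order. Of genes changed by 2 it recovered 81%, 81% and 82%. False calls made up 7.79%, 5.88% and 8.55% of its calls, and 16.1%, 20.2% and 20.2% of those of DESeq2. A simulated shift of 0.5 in complex I was called by camera with an estimated correlation too (adjusted p = 0.000136, 0.00601 and 0.000155). Of the 34 lists left unshifted, camera at the preset correlation called 3, 1 and 3. Simulated genes varied independently of each other, so these values do not show how the list tests perform where members move together. The 200 changed genes are also far fewer than the 5417 and 6371 called for allogeneic against syngeneic and naive libraries.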

Results

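RNA was sequenced from colonic epithelial cells of 9 C57BL/B6 mice, the strain as the labels write it. Of these, 6 had received total body irradiation (1000 cGy on day -1) and, on day 0, CD90.2-positive T cells with bone marrow cells. Donors were C57BL/B6 for the 3 syngeneic recipients. For the 3 allogeneic recipients they were BALB/c, a strain with other major histocompatibility complex (MHC) alleles. Colonic cells were taken on day 7. The 3 naive mice were 9 weeks old and received no transplant. Transfer of mismatched donor T cells after irradiation is a standard mouse model of graft-versus-host disease, in which the colonic epithelium is a target tissue.

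Gene counts per library ran from 19961346 to 30214449. They were 22990705, 26374873 and 19961346 in naive replicates 1 to 3. Syngeneic replicates 1 to 3 had 22423292, 26236242 and 29704422, and allogeneic replicates 1 to 3 had 25076386, 30214449 and 26937380. Gene levels are given as CPM, counts per 1000000 counts of a library after scaling by its TMM factor. A count of 0 allows up to 3 counts, or 0.0993 to 0.15 per 1000000 unscaled counts. Principal component 1 took 68.7% of the variance, with the allogeneic libraries at 49.5 to 103.8 and every other library at -25.2 or lower. Component 2 (10.5%) held syngeneic replicates 1 and 2 at -37 and -47.2. Syngeneic replicate 3 lay at 24.5, next to the naive libraries (9.64 to 21.02). Xist, the X-inactivation transcript, averaged 417 CPM in naive, 356 in syngeneic and 292 in allogeneic libraries.

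**Figure D1:**
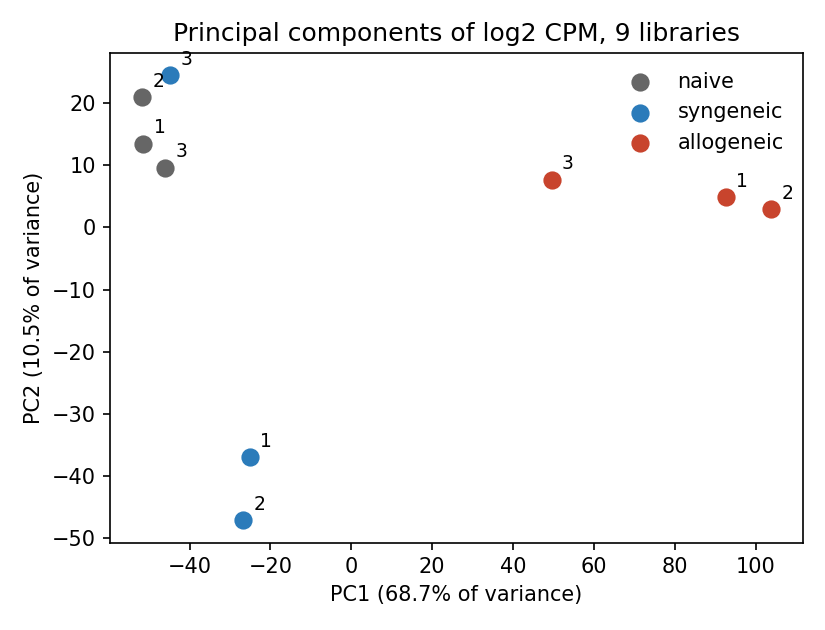
Principal components 1 and 2 of log2 CPM over the genes tested, with 1 point per library, coloured by group and marked with its replicate number. Allogeneic libraries lie at 49.5 or above on component 1, and syngeneic replicate 3 lies beside the naive libraries on component 2.

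Allogeneic against syngeneic recipients asks what the donor strain changed, since both groups were irradiated and transplanted. The antigen presentation machinery stood far higher in the allogeneic libraries. Cd74, the MHC class II invariant chain (Ensembl gene ENSMUSG00000024610, GRCm38 chromosome 18, 60803848 to 60812652), averaged 1810 ± 317 CPM (SD, n = 3) against 13.3 ± 4.85 in syngeneic libraries. Its log2 fold change was 7.10 ± 0.38 (SE, edgeR adjusted p = 1.98e-05). Ido1, which degrades tryptophan, averaged 768 ± 340 against 3.51 ± 1.07 CPM, and the chemokine gene Cxcl9 113 ± 55.3 against 0.979 ± 0.21 CPM. Among the genes that fell furthest were the carboxylesterases Ces1d (log2 fold change -4.92 ± 0.62) and Ces2a (-3.44 ± 0.78) and the sulfotransferase Sult1c2 (-4.27 ± 0.54). Across 14384 genes tested, 5417 changed, of which 2732 were higher and 2685 lower in allogeneic libraries.

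All 8 measured MHC class II genes rose (8 adjusted over the list alone), with a median log2 fold change of 6.47. Camera, which compares a list with all other genes, passed this list (adjusted p = 2.21e-45), and it still passed with an estimated correlation (adjusted p = 0.028). The members include H2-Aa (6.80 ± 0.31, 695 ± 98.8 against 6.28 ± 2.31 CPM) and Ciita, the master activator of class II transcription (6.57 ± 0.31). Genes of MHC class I presentation rose in 19 of 19 cases (19 adjusted over the list alone, median 2.11). The class I list had camera adjusted p = 3.6e-35, and adjusted p = 0.135 with an estimated correlation. Tap1, a peptide transporter subunit, rose by 3.93 ± 0.29 and the immunoproteasome subunit Psmb8 by 3.79 ± 0.29. H2-Q4 and H2-Q7 also rose (2.57 ± 0.17 and 4.28 ± 0.29), but these paralogues share sequence, so their separate values are uncertain.

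Interferon-gamma response genes rose in 23 of 23 cases (23 adjusted over the list alone, median 3.89). The interferon-gamma list had camera adjusted p = 1.41e-45, and adjusted p = 0.103 with an estimated correlation. The chemokine gene Cxcl10 rose by 4.92 ± 0.29. Of 20 type I interferon genes, 18 rose (18 adjusted over the list alone, median 2.29), such as Ifit2 (5.93 ± 0.61) and Isg15 (3.99 ± 0.51). The type I list had camera adjusted p = 1.67e-13, and adjusted p = 0.47 with an estimated correlation.

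Transcripts of T and natural killer cells were higher in the same libraries. Of 24 markers, 22 rose (23 adjusted over the list alone, median 2.69). Camera gave these markers adjusted p = 5.82e-14, and adjusted p = 0.47 with an estimated correlation. Their summed level, per 1000000 unscaled counts, was 831 ± 268 in allogeneic, 145 ± 87.8 in syngeneic and 92.8 ± 21.1 in naive libraries. Pdcd1 and Icos, receptors of activated T cells, averaged 48.2 ± 27.3 and 21.3 ± 10.8 CPM in allogeneic libraries. In syngeneic libraries they averaged 0.201 ± 0.0924 and 0.0914 ± 0.0455 CPM. That Icos level lies under the 3-count limit of these libraries (0.101 to 0.134 per 1000000 unscaled counts), so the size of its rise is uncertain. Ctla4 rose by 6.80 ± 0.51.

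Myeloid markers rose in 7 of 19 cases (7 adjusted over the list alone, median 0.93), among them Ccr2 (4.12 ± 0.60) and S100a9 (7.999 ± 6.55 against 0.21 ± 0.146 CPM). The myeloid list had camera adjusted p = 0.00554, and adjusted p = 0.838 with an estimated correlation. It did not pass without syngeneic replicate 3 (median 0.67, adjusted p = 0.0839), among genes at 10 CPM or more (2.045, 0.15) or by fry (0.105), within 3.38e-05 to 0.838 over all alternatives. At 10 CPM or more, members such as S100a9 drop out and the median was higher, so that lost call does not show a smaller change. The 5 measured B and plasma cell markers did not pass (0 over all genes and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.876). Stromal, muscle and endothelial genes rose in 2 and fell in 3 of 13 cases (2 and 7 adjusted over the list alone, adjusted p = 0.542). Genes of enteric neurons and glia rose in 1 and fell in 1 of 5 (1 and 2 adjusted over the list alone, adjusted p = 0.653). Erythroid genes fell in 3 of 6 cases (5 adjusted over the list alone, median -3.93), and the call depended on the setting. Camera gave adjusted p = 0.066, against 0.00915 with the replicate block, 0.00317 with the 2 groups alone, 0.0392 with no filter and 0.0296 without syngeneic replicate 2 (0.00317 to 0.799 over all alternatives).

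Cell death genes rose in 10 of 20 cases (11 adjusted over the list alone, median 0.63). They include Mlkl and Zbp1 of the necroptosis pathway (1.98 ± 0.20 and 4.18 ± 0.44) and the death ligand gene Tnfsf10 (2.56 ± 0.17). The cell death list had camera adjusted p = 5.9e-07, and adjusted p = 0.506 with an estimated correlation. Its median was 0.41 without syngeneic replicate 3. Cell cycle genes rose in 22 of 30 cases (27 adjusted over the list alone, median 1.002), with Rrm2, a ribonucleotide reductase subunit, at 1.91 ± 0.21. The cell cycle list had camera adjusted p = 3.64e-10, and adjusted p = 0.62 with an estimated correlation. In these libraries the T and natural killer cell sum given above was 5.73 times that of syngeneic libraries.

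Genes of the unfolded protein response rose in 15 of 18 cases (17 adjusted over the list alone, median 0.61), with the chaperone gene Hspa5 at 1063 ± 103 against 441 ± 51.5 CPM. The unfolded protein list had camera adjusted p = 1.78e-08, and adjusted p = 0.285 with an estimated correlation. In the integrated stress response list 11 of 19 members rose and Sesn2 fell (13 and 1 adjusted over the list alone, median 1.35). Camera gave that list adjusted p = 0.00216, and adjusted p = 0.838 with an estimated correlation. Its median was 0.57 without allogeneic replicate 2, and it did not pass by fry (adjusted p = 0.153). Several that rose are enzymes of serine and one-carbon metabolism: Phgdh (2.56 ± 0.44), Psat1 (2.93 ± 0.53) and Shmt2 (1.85 ± 0.35). The p53 targets rose in 3 and fell in 4 of 20 cases (4 and 5 adjusted over the list alone, camera adjusted p = 0.876). Hypoxia targets rose in 1 and fell in 2 of 15 (1 and 2 adjusted over the list alone, adjusted p = 0.653). Immediate early genes of tissue dissociation rose in 1 and fell in 1 of 14 (1 and 0 adjusted over the list alone, adjusted p = 0.653).

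In energy metabolism, the 4 subunits of respiratory complex II, the succinate dehydrogenase, did not pass the test (0 over all genes, 0 adjusted over the list alone). Camera gave them adjusted p = 0.984 and pointed upward, against a negative median and mean (-0.007 and -0.002). Sdha averaged 534 ± 28.9 CPM in allogeneic and 516 ± 35.3 in syngeneic libraries, a log2 fold change of 0.05 ± 0.10 (edgeR adjusted p = 0.719). Sdhb, Sdhc and Sdhd stood at -0.07 ± 0.08, 0.10 ± 0.09 and -0.09 ± 0.11. In complex I, 3 nuclear-encoded members rose and 6 fell of 36 (0 and 4 adjusted over the list alone, camera adjusted p = 0.653), among them Ndufa7 (-0.57 ± 0.09) and Ndufa1 (-0.80 ± 0.12). In complex III, 1 fell of 9 (0 adjusted over the list alone, adjusted p = 0.876). In complex IV, 2 fell of 12 (1 adjusted over the list alone, adjusted p = 0.399). In complex V, 1 rose of 15 (0 adjusted over the list alone, adjusted p = 0.758), with a median of -0.007 while the mean (0.05) and the test pointed upward.

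Transcripts of the mitochondrial genome fell in 9 of 13 cases (12 adjusted over the list alone, median -1.46), mt-Co1 from 123900 ± 40960 to 37770 ± 18410 CPM. The mitochondrially encoded list had camera adjusted p = 0.000205, and adjusted p = 0.751 with an estimated correlation. By fry it did not pass (adjusted p = 0.06). These 13 genes took 17.6% ± 3.82 of all counts in syngeneic, 6.6% ± 3.27 in allogeneic and 12.1% ± 3.31 in naive libraries (SD, n = 3).

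**Figure D2:**
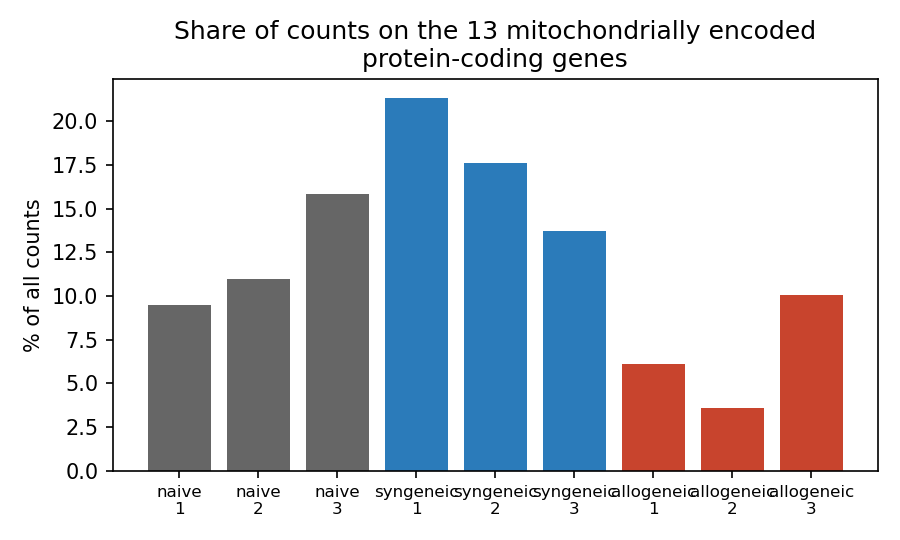
Percent of all counts on the 13 mitochondrially encoded protein-coding genes, with 1 bar per library. Syngeneic libraries lie at 13.7% to 21.4%, naive libraries at 9.496% to 15.8% and allogeneic libraries at 3.595% to 10.1%.

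Fatty acid oxidation and ketogenesis genes fell in 14 of 27 cases and Acadl rose (14 and 1 adjusted over the list alone, median -0.47). The fatty acid list had camera adjusted p = 0.000263, and adjusted p = 0.498 with an estimated correlation. Acaa2 and Hadh, enzymes of beta-oxidation, stood at -1.03 ± 0.12 and -1.01 ± 0.13. Cholesterol synthesis genes rose in 14 of 19 cases (15 adjusted over the list alone, median 0.77). The cholesterol list had camera adjusted p = 1.27e-06, and adjusted p = 0.62 with an estimated correlation. Glycolysis genes rose in 9 of 18 cases and Pfkl fell (10 and 1 adjusted over the list alone, median 0.52), with Pgk1 at 0.94 ± 0.13. The glycolysis list had camera adjusted p = 0.00596, and adjusted p = 0.684 with an estimated correlation. Without syngeneic replicate 3 its adjusted p was 0.0549, within 0.000757 to 0.684 over all alternatives. In the tricarboxylic acid cycle list 8 of 18 members rose and 2 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.531), with Cs, the citrate synthase, at 0.54 ± 0.13.

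Crypt stem cell genes fell in 5 of 18 cases (5 adjusted over the list alone, median -0.52), with Sox9 at 32.9 ± 2.3 against 64.2 ± 5.31 CPM. The stem cell list had camera adjusted p = 0.0457, and adjusted p = 0.838 with an estimated correlation. Without syngeneic replicate 3 its median was -0.21 (adjusted p = 0.321). Without allogeneic replicate 2 it was -0.38 (0.059), without allogeneic replicate 3 it was -0.48 (0.083), and fry gave 0.0764, within 0.00768 to 0.838 over all alternatives. Of 16 goblet cell genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.256), Klk1 from 797 ± 22.4 to 126 ± 77.2 CPM. The goblet list passed without allogeneic replicate 3 (median -0.60, adjusted p = 0.0325, the lowest of 0.0325 to 0.946 over all alternatives). Colonocyte genes went both ways, with 5 of 20 higher and 3 lower (5 and 3 adjusted over the list alone). Camera pointed upward for them (adjusted p = 0.876) against a median of -0.02 and a mean of -0.07. Krt20, a keratin of surface cells, rose by 1.23 ± 0.20, whereas Slc37a2 fell by 2.82 ± 0.50.

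Tight junction genes rose in 3 and fell in 4 of 18 cases (4 and 4 adjusted over the list alone, camera adjusted p = 0.542), and Ocln fell by 0.46 ± 0.10. Among 20 antimicrobial and defence genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, adjusted p = 0.876). Nos2, the inducible nitric oxide synthase, rose by 5.22 ± 0.60, and Il18 fell from 68.4 ± 5.94 to 10.4 ± 1.62 CPM. Enteroendocrine genes fell in 1 of 15 cases (0 adjusted over the list alone, adjusted p = 0.244). Tuft cell genes rose in 1 of 11 (0 adjusted over the list alone, adjusted p = 0.758), with mean and test upward (0.17) and a median of -0.07. The Paneth and small intestinal list rose in 1 and fell in 1 of 9 cases (1 and 1 adjusted over the list alone, adjusted p = 0.689).

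**Figure D3:**
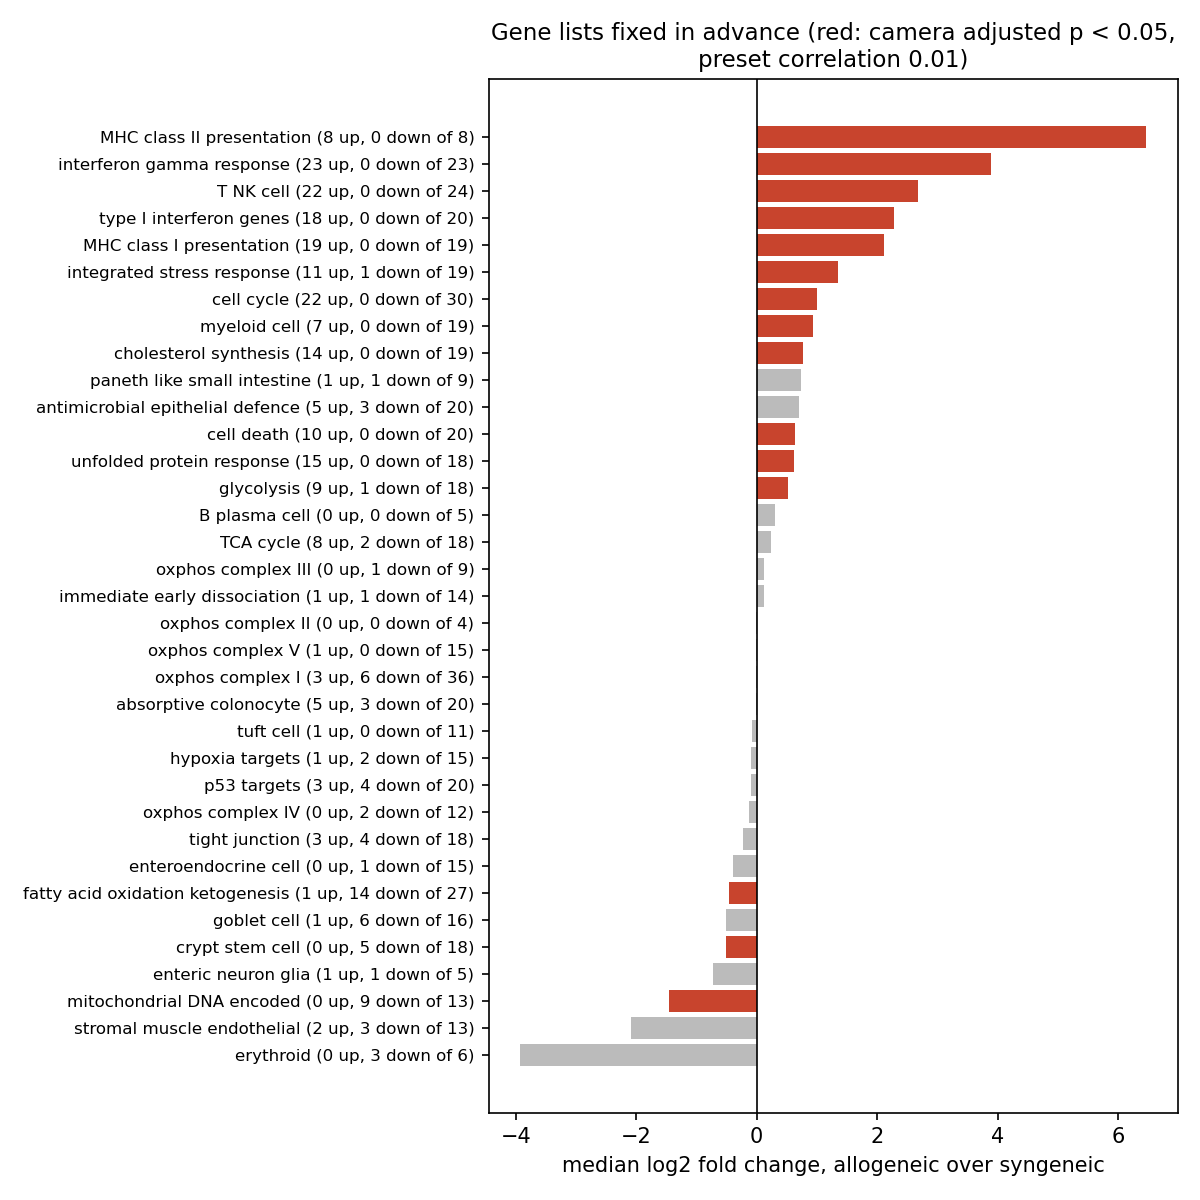
Median log2 fold change, allogeneic over syngeneic, of the measured members of each gene list, with 1 bar per list. Bars of lists past camera at the preset correlation of 0.01 are red, from MHC class II (6.47) to mitochondrially encoded genes (-1.46), and labels give how many members rose and fell.

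Tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over all genes. The count of changed genes was 3588 when only the 6 libraries compared were fitted, and 3534 without allogeneic replicate 1. In 48.1% of genes the groups did not overlap, where chance gives 10%.

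Syngeneic recipients against naive mice address what irradiation and transplant did without a donor mismatch. By edgeR, 1 of 14384 genes passed. Fer1l4, a ferlin-family gene named here after its values were seen, stood at 7.44 ± 0.586 CPM in syngeneic against 1.96 ± 0.505 in naive libraries (SD, n = 3). Its log2 fold change was 1.93 ± 0.18 (edgeR adjusted p = 0.0182), higher in 3 of 3 libraries. At an unadjusted p below 0.05 there were 1715 genes, and DESeq2 called 236. The groups did not overlap in 20.3% of genes, where chance gives 10%. The 4 complex II genes stood at 0.01 ± 0.10 (Sdha), 0.25 ± 0.08 (Sdhb), 0.16 ± 0.09 (Sdhc) and 0.12 ± 0.11 (Sdhd), none past the test (0 adjusted over the list alone, camera adjusted p = 0.17). The complex II list passed without syngeneic replicate 1 (median 0.20, adjusted p = 0.0371, within 0.0371 to 0.701 over all alternatives). Cd74 stood at 13.3 ± 4.85 against 15.05 ± 4.44 CPM in naive libraries, and the class II list did not pass (0 adjusted over the list alone, median -0.12, camera adjusted p = 0.373). The class II list passed without naive replicate 2 (-0.345, 0.0277) and with no filter (-0.21, 0.0427), within 0.0277 to 0.966 over all alternatives. With no filter it also holds H2-Oa and H2-Ob, at 0 to 8 counts in each naive and syngeneic library, so that call includes genes near the floor.

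Camera passed 16 lists although 0 of their members passed over all genes by edgeR, and 0 lists passed with an estimated correlation. By fry 3 lists passed, complexes I, III and V (adjusted p = 0.0205, 0.0287 and 0.0287). Complex I had 8 of 36 members higher adjusted over the list alone (median 0.20). The complex I list had camera adjusted p = 3.71e-09, and adjusted p = 0.275 with an estimated correlation. Complexes III, IV and V (0 adjusted over the list alone in each) had medians of 0.22, 0.19 and 0.16 and camera adjusted p = 0.00159, 0.00589 and 0.000207. With an estimated correlation these were adjusted p = 0.318, 0.637 and 0.298. Mitochondrially encoded genes had a median of 0.62 (0 adjusted over the list alone, camera adjusted p = 0.000316, and adjusted p = 0.655 with an estimated correlation). That median was 0.34 without naive replicate 1, 1.05 without naive replicate 3 and 0.28 without syngeneic replicate 1. Glycolysis genes had 4 of 18 higher adjusted over the list alone (median 0.37, camera adjusted p = 1.57e-08, and adjusted p = 0.275 with an estimated correlation). Hypoxia targets had 3 of 15 higher adjusted over the list alone (median 0.26, camera adjusted p = 0.000524, and adjusted p = 0.275 with an estimated correlation), and their median was 0.15 without syngeneic replicate 1.

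Immediate early genes had 5 of 14 lower adjusted over the list alone (median -0.46), with Fos at 588 ± 177 against 763 ± 109 CPM. Camera gave the immediate early list adjusted p = 3.56e-06, and adjusted p = 0.275 with an estimated correlation. Crypt stem cell genes had 1 of 18 lower adjusted over the list alone (median -0.34, camera adjusted p = 9.06e-05, and adjusted p = 0.552 with an estimated correlation), with a median of -0.54 without syngeneic replicate 3. Goblet cell genes had 0 adjusted over the list alone (median -0.20, camera adjusted p = 0.00781, and adjusted p = 0.68 with an estimated correlation). Muc2, the main colonic mucin, averaged 1357 ± 188 against 2662 ± 641 CPM (edgeR adjusted p = 0.332). Of 5 B and plasma cell markers 3 were lower adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.637 with an estimated correlation). Igha averaged 1.16 ± 0.56 against 7.15 ± 5.87 CPM. The goblet median was -0.34 without naive replicate 2 and -0.40 without syngeneic replicate 1, and without syngeneic replicate 3 the list did not pass (-0.10, adjusted p = 0.426, within 1.52e-06 to 0.68 over all alternatives). The B and plasma cell median of -2.64 became -1.35, -1.62 and -1.55 without naive replicate 1, naive replicate 2 and syngeneic replicate 1. That list did not pass without naive replicate 3 (-0.78, adjusted p = 0.101), syngeneic replicate 3 (-0.98, 0.455) or the mitochondrially encoded genes (-1.31, 0.158), within 0.000178 to 0.637 over all alternatives. The low-count filter was run anew in each fit (14384 genes with all libraries, 14396 without the mitochondrially encoded genes). It kept 5 of 14 listed markers with all libraries, so a marker near the floor that enters can shift these medians. The moves are therefore not put down to the library or genes left out.

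The other lists that camera passed pointed upward. MHC class I had a median of 0.31 (0 adjusted over the list alone, camera adjusted p = 0.000854, and adjusted p = 0.68 with an estimated correlation). The interferon-gamma response had 0.38 (1 adjusted over the list alone, adjusted p = 1.39e-05, and adjusted p = 0.637 with an estimated correlation). Cell death genes had 0.17 (2 adjusted over the list alone, adjusted p = 0.00195, and adjusted p = 0.655 with an estimated correlation). Fatty acid oxidation had 0.16 (0 adjusted over the list alone, adjusted p = 0.00781, and adjusted p = 0.637 with an estimated correlation). Colonocyte genes had 0.22 (0 adjusted over the list alone, adjusted p = 0.0165, and adjusted p = 0.655 with an estimated correlation).

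Left-out libraries moved these 5 lists. Without syngeneic replicate 2 the class I median was 0.10 and the list did not pass (adjusted p = 0.243, within 4.91e-08 to 0.68 over all alternatives), while without syngeneic replicate 3 the median was 0.52. The interferon-gamma median was 0.58, 0.23 and 0.63 without naive replicate 3, syngeneic replicate 2 and syngeneic replicate 3. For cell death it was 0.11 and 0.28 without syngeneic replicate 1 and syngeneic replicate 3. The fatty acid list did not pass without naive replicate 3 (0.11, adjusted p = 0.0889) or syngeneic replicate 2 (0.08, 0.0599), within 0.00162 to 0.637 over all alternatives. The colonocyte list did not pass without naive replicate 1 (0.175, 0.154) or syngeneic replicate 1 (0.135, 0.127), within 0.00197 to 0.655, and had a median of 0.14 without syngeneic replicate 2.

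Of the lists that did not pass with all libraries, several had 0 members adjusted over the list alone. By median and camera adjusted p these were T and natural killer cells (0.38, 0.219), myeloid cells (0.53, 0.17), type I interferon (0.15, 0.188) and cholesterol synthesis (0.15, 0.0797). The same held for the tricarboxylic acid cycle (0.045, 0.241), the unfolded protein response (0.09, 0.394), the integrated stress response (0.14, 0.812) and enteroendocrine cells (-0.025, 0.787). It also held for tuft cells (-0.06, 0.703), enteric neurons and glia (0.20, 0.576) and stromal genes (1.06, 0.0537). Antimicrobial genes had 2 higher and 2 lower adjusted over the list alone (0.16, 0.238). The p53 targets had 1 higher (0.04, 0.812) and tight junctions 1 lower (0.07, 0.868), both adjusted over the list alone. The Paneth and small intestinal list (2 higher adjusted over the list alone, adjusted p = 0.238) tested upward against a median of -0.76 and a mean of -0.32. The erythroid list (1 higher adjusted over the list alone, adjusted p = 0.812) tested upward against -0.75 and -0.43.

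Some of these lists passed when a library was left out. Without syngeneic replicate 3, T and natural killer cell markers had a median of 0.81 (camera adjusted p = 4.36e-05), myeloid markers 0.92 (0.00677), type I interferon genes 0.46 (0.0012) and stromal genes 1.52 (0.00212). Without naive replicate 3 the same lists had 0.58 (0.0184), 0.67 (0.0357), 0.40 (0.00882) and 1.61 (0.000551). Stromal genes passed without naive replicate 1 (1.004, 0.0162) and with RLE size factors (0.0489) too. Cholesterol synthesis passed without naive replicate 1 (0.22, 0.00681), without syngeneic replicate 2 (0.24, 0.000432) and with no filter (0.0476). The Paneth and small intestinal list had a median of 0.49 without naive replicate 1 (0.0236) and 0.71 among genes at 10 CPM or more (0.00583). Over all alternatives adjusted p ran from 4.36e-05 to 0.913 for T and natural killer cells, 0.00677 to 0.863 for myeloid cells and 0.0012 to 0.958 for type I interferon. It ran from 0.000551 to 0.682 for stromal genes, 0.000432 to 0.987 for cholesterol synthesis and 0.00583 to 0.991 for the Paneth and small intestinal list.

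Without syngeneic replicate 3, 395 genes passed (271 higher and 124 lower). Without naive replicate 1, naive replicate 2 or syngeneic replicate 1 the count by edgeR was 0, against 1715 at an unadjusted p below 0.05 and 236 by DESeq2 in all libraries, and without syngeneic replicate 2 it was 4. The cell cycle list (0 adjusted over the list alone) had a median of 0.065 (camera adjusted p = 0.394). It turned to -0.41 without syngeneic replicate 3 (adjusted p = 0.000135) and stood at 0.32 without syngeneic replicate 2 (adjusted p = 2.22e-08).

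Allogeneic recipients and naive mice differed by the whole procedure with a mismatched donor. Interferon-inducible and T cell genes were far higher. Ido1 averaged 768 ± 340 against 1.25 ± 1.43 CPM (log2 fold change 9.37 ± 0.78, edgeR adjusted p = 0.000102), Tgtp1 76.4 ± 26.3 against 0.244 ± 0.0914 CPM and Pdcd1 48.2 ± 27.3 against 0.178 ± 0.157 CPM. The stem cell marker Lgr5 fell by 2.33 ± 0.42 on the log2 scale and Muc2 fell by 1.68 ± 0.33. Sycn, a secretory granule gene, fell by 5.11 ± 0.67, from 422 ± 45.4 to 12.3 ± 10.7 CPM. By edgeR 6371 of 14384 genes changed, 3215 higher and 3156 lower, and the groups did not overlap in 59.9% of genes, where chance gives 10%.

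MHC class II genes rose in 8 of 8 cases (8 adjusted over the list alone, median 6.53, camera adjusted p = 2.93e-35, and adjusted p = 0.0523 with an estimated correlation). MHC class I genes rose in 19 of 19 (19 adjusted over the list alone, 2.30, adjusted p = 5.35e-34, and adjusted p = 0.165 with an estimated correlation). Interferon-gamma genes rose in 23 of 23 (23 adjusted over the list alone, 4.27, adjusted p = 1.02e-42, and adjusted p = 0.129 with an estimated correlation). Type I interferon genes rose in 19 of 20 (20 adjusted over the list alone, 2.55, adjusted p = 1.12e-12, and adjusted p = 0.409 with an estimated correlation). T and natural killer cell markers rose in 22 of 24 (22 adjusted over the list alone, 3.52, adjusted p = 6.87e-13, and adjusted p = 0.409 with an estimated correlation). Myeloid markers rose in 11 of 19 and Ms4a7 fell (11 and 1 adjusted over the list alone, 1.93, adjusted p = 0.00248, and adjusted p = 0.756 with an estimated correlation). The myeloid call was lost among genes at 10 CPM or more (adjusted p = 0.15) and by fry (0.0651), within 1.6e-05 to 0.756 over all alternatives. Over the members left at 10 CPM or more the median was higher (2.29), so that loss does not show a smaller change.

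Cell death genes rose in 15 of 20 cases (15 adjusted over the list alone, median 0.91, camera adjusted p = 9.91e-09, and adjusted p = 0.409 with an estimated correlation). Cell cycle genes rose in 25 of 30 (25 adjusted over the list alone, 1.09, adjusted p = 2.55e-09, and adjusted p = 0.636 with an estimated correlation). Unfolded protein response genes rose in 14 of 18 (15 adjusted over the list alone, 0.79, adjusted p = 6.34e-08, and adjusted p = 0.333 with an estimated correlation). Integrated stress response genes rose in 12 of 19 (13 adjusted over the list alone, 1.52, adjusted p = 0.00532, and adjusted p = 0.763 with an estimated correlation). Their median was 0.63 without allogeneic replicate 2, and by fry they did not pass (adjusted p = 0.119). Cholesterol synthesis genes rose in 16 of 19 (16 adjusted over the list alone, 0.88, adjusted p = 3e-07, and adjusted p = 0.592 with an estimated correlation). Glycolysis genes rose in 14 of 18 and Pfkm fell (14 and 1 adjusted over the list alone, 0.84, adjusted p = 1.23e-06, and adjusted p = 0.389 with an estimated correlation). The lactate transporter Slc16a3 rose by 2.98 ± 0.31.

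Crypt stem cell genes fell in 11 of 18 cases (11 adjusted over the list alone, median -0.75, camera adjusted p = 0.000508, and adjusted p = 0.592 with an estimated correlation). Goblet cell genes fell in 7 of 16 and Ang4 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0346, and adjusted p = 0.763 with an estimated correlation). Fatty acid oxidation genes fell in 11 and rose in 3 of 27 (11 and 3 adjusted over the list alone, adjusted p = 0.0436, and adjusted p = 0.756 with an estimated correlation). The goblet list did not pass without naive replicate 3 (0.0545) or allogeneic replicate 1 (0.0539), with the 2 groups alone (0.104) or by fry (0.0628), within 0.00273 to 0.763 over all alternatives. The fatty acid list did not pass with the replicate block (0.0598), or without naive replicate 2 (0.0751), allogeneic replicate 1 (0.104) or allogeneic replicate 3 (0.0678), within 0.0104 to 0.756 over all alternatives. Antimicrobial genes rose in 9 and fell in 3 of 20 (9 and 3 adjusted over the list alone, adjusted p = 0.612), with Il18 at 10.4 ± 1.62 against 101.5 ± 4.86 CPM. Of 5 B and plasma cell markers 3 fell (3 adjusted over the list alone, adjusted p = 0.423), and Igha fell by 3.57 ± 0.85 to 0.599 ± 0.44 CPM.

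Among nuclear-encoded respiratory genes, 11 of 36 rose and 3 fell in complex I (10 and 3 adjusted over the list alone, camera adjusted p = 0.0979). In complex V 7 of 15 rose (7 adjusted over the list alone, adjusted p = 0.0778), such as Atp5g1 at 301 ± 2.1 against 211 ± 16.7 CPM. The complex V list passed without naive replicate 2 (median 0.32, adjusted p = 0.0419) and with no filter (0.0361), within 0.00283 to 0.696 over all alternatives. In complex III 4 of 9 rose (5 adjusted over the list alone, adjusted p = 0.201). In complex IV 1 rose and 2 fell of 12 (0 and 1 adjusted over the list alone, adjusted p = 0.931), where the median (0.03) and test pointed upward and the mean was -0.008. Of complex II, Sdhc rose by 0.26 ± 0.09 (edgeR adjusted p = 0.0366), from 206 ± 5.37 to 247 ± 6.76 CPM. Sdha stood at 0.06 ± 0.10, Sdhb at 0.18 ± 0.08 and Sdhd at 0.03 ± 0.11 (complex II list 1 over all genes, 0 adjusted over the list alone, camera adjusted p = 0.592). The Sdhc call was lost in 10 of 13 alternatives. By edgeR its adjusted p was 0.0652 to 0.102 without each of the 6 libraries in turn, 0.0936 with no filter, 0.0693 among genes at 10 CPM or more, 0.0558 with the 2 groups alone and 0.0522 with the replicate block (0.00588 to 0.102 over all alternatives). By fry complexes I, III and V passed (adjusted p = 0.00716, 0.0067 and 0.00283).

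The mitochondrially encoded list had 0 members past over all genes and 0 adjusted over the list alone (median -0.89, camera adjusted p = 0.0778), and its call depended on the setting. It passed without naive replicate 1 (-1.09, adjusted p = 0.00517), naive replicate 2 (-0.96, 0.0343) or allogeneic replicate 3 (-1.23, 0.0159) and with no filter (-0.88, 0.0324), within 0.00517 to 0.778 over all alternatives.

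Colonocyte genes rose in 6 and fell in 4 of 20 cases (8 and 4 adjusted over the list alone, camera adjusted p = 0.287). Hypoxia targets rose in 3 and fell in 1 of 15 (3 and 1 adjusted over the list alone, adjusted p = 0.495). Immediate early genes rose in 1 and fell in 5 of 14 (1 and 6 adjusted over the list alone, adjusted p = 0.237), and tricarboxylic acid cycle genes rose in 9 and fell in 2 of 18 (10 and 3 adjusted over the list alone, adjusted p = 0.225). Stromal genes rose in 2 of 13 (2 adjusted over the list alone, adjusted p = 0.931). Genes of enteric neurons and glia rose in 1 and fell in 1 of 5 (1 and 1 adjusted over the list alone, adjusted p = 0.78), and erythroid genes rose in 1 and fell in 5 of 6 (1 and 5 adjusted over the list alone, adjusted p = 0.195). The erythroid list passed without naive replicate 2 (median -5.11, adjusted p = 0.00227, the lowest of 0.00227 to 0.814 over all alternatives). Enteroendocrine genes fell in 2 of 15 (0 adjusted over the list alone, adjusted p = 0.201) and tuft cell genes rose in 1 of 11 (0 adjusted over the list alone, adjusted p = 0.895).

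In 3 further lists the median, mean and test differed in sign. The p53 targets rose in 5 and fell in 4 of 20 cases (5 and 5 adjusted over the list alone), with a median of 0.07, a mean of -0.06 and a downward test (camera adjusted p = 0.95). Tight junction genes rose in 2 and fell in 5 of 18 (2 and 5 adjusted over the list alone), with 0.09, -0.08 and a downward test (adjusted p = 0.561). The Paneth and small intestinal list rose in 2 of 9 (2 adjusted over the list alone), with -0.21, 0.34 and an upward test (adjusted p = 0.423).

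**Figure D4:**
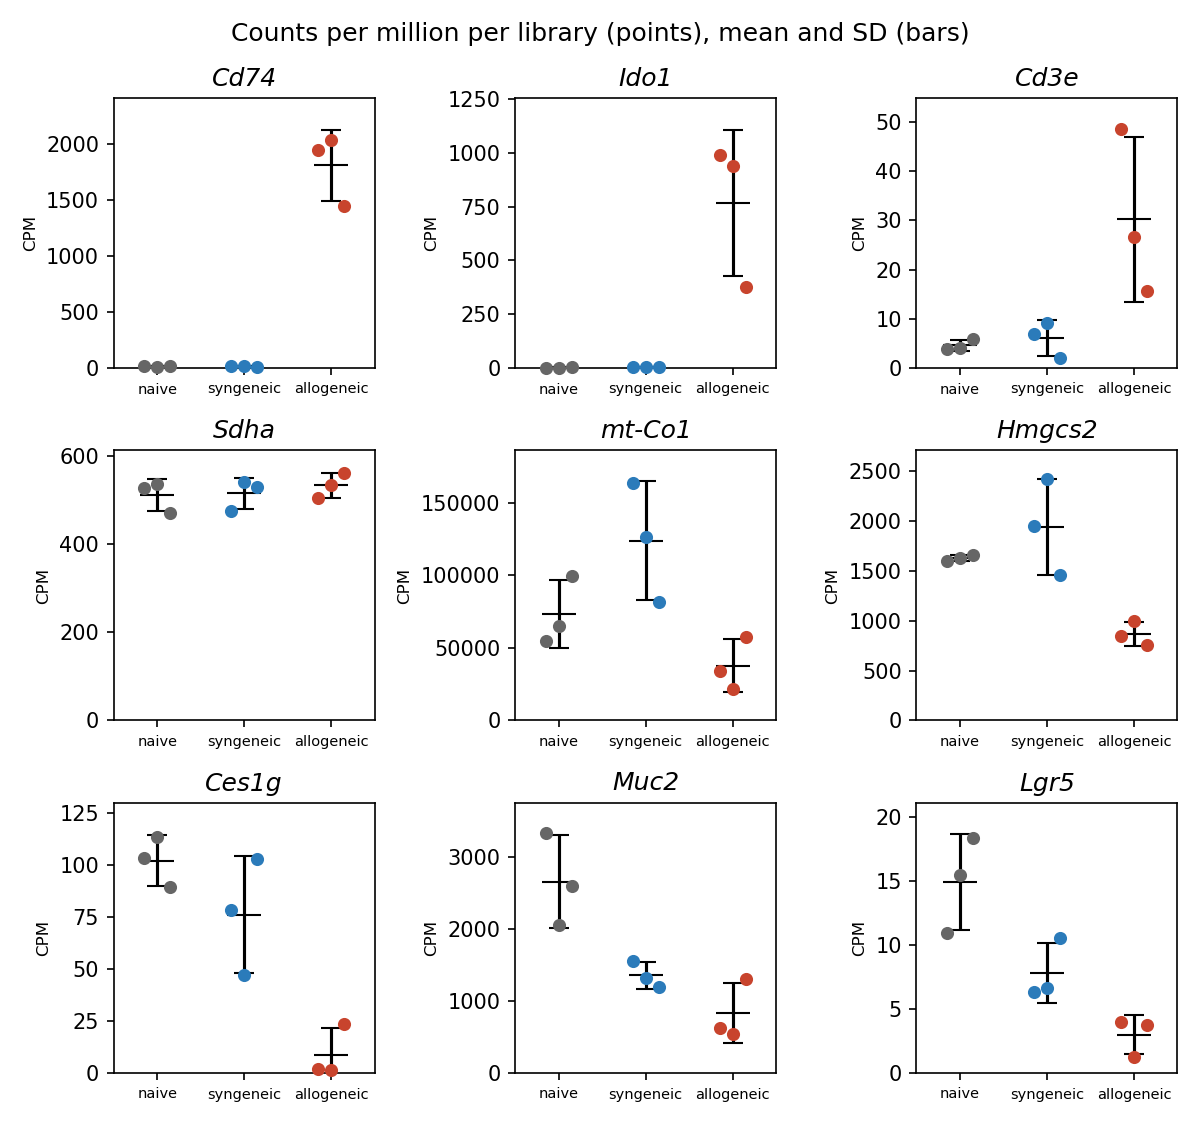
CPM of 9 named genes, with 1 point per library, horizontal marks for the group mean and error bars for 1 SD (n = 3). Cd74 averaged 1810 CPM in allogeneic libraries against 13.3 and 15.05 in syngeneic and naive libraries, while Sdha averaged 534, 516 and 512.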

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

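Leaving out the mitochondrially encoded genes was chosen after the results were seen, and the other alternatives were planned. Main counts of changed genes were 5417 for allogeneic against syngeneic, 1 for syngeneic against naive and 6371 for allogeneic against naive. In that order, a threshold of 0.01 gave 2503, 0 and 3641 genes, and a change of at least 1 on the log2 scale 2335, 1 and 2838, both by construction. Fitting only the groups compared gave 3588 (3574 of them shared), 8 and 6644. The count fell where naive libraries left the fit and rose in the other comparisons, so fewer libraries behind each spread cannot alone explain it. In the main fit naive libraries, which correlated at 0.986 to 0.990 with each other, also set the spread of allogeneic against syngeneic. Syngeneic libraries correlated at 0.968 to 0.987 with each other and allogeneic libraries at 0.969 to 0.985. Why the counts moved was not tested. The replicate block, which no label calls a pairing, gave 5134, 0 and 6116. Libraries sharing a replicate number had correlations of -0.189 to 0.208 between their deviations from group means, and 0 of 9 libraries correlated best with their own number in both other groups. Pairing by animal number was not tested. For syngeneic against naive, DESeq2 called 236 genes and edgeR without a filter 7, while 1715 had an unadjusted p below 0.05; the cause was not tested. Leaving out each library gave 3534 to 5943, 0 to 395 and 4723 to 6831 genes; the lowest first count came without allogeneic replicate 1, the 395 without syngeneic replicate 3, 4 without syngeneic replicate 2, and 0 without naive replicate 1, naive replicate 2 or syngeneic replicate 1. Camera called 15, 16 and 15 lists, 1, 0 and 0 with an estimated correlation, 11, 3 and 15 by fry, and 12 to 16, 16 to 19 and 13 to 17 with each library left out. The 1 result that reversed was the cell cycle list in syngeneic against naive, with a median of -0.41 without syngeneic replicate 3 and 0.32 without syngeneic replicate 2; the cause was not tested. Of 5864 alternative values of 449 results, each a gene or list in 1 comparison, 5558 kept the side of the threshold (84 of these with a changed sign), 259 lost a call, 46 gained one and 1 reversed. Many of the genes were picked by p or size of change in the main fit, which favours keeping a call. For syngeneic against naive, 933 of 940 gene values only stayed uncalled. The totals therefore do not measure how stable genes in general are. Pseudocounts were not varied, as the values are counts. At 3 libraries a group, depth limits statements on genes under about 0.15 CPM on unscaled totals.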

Other observations

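Families of genes sharing a symbol stem, the tests of a wrong label, of MHC class II, of carry-over and of both genomes' output were chosen after the results were seen; the splits, depth, mitochondrial-share and epithelial-cell tests were planned before. Among 168 stems with at least 10 members, camera passed 21 in allogeneic against syngeneic libraries. The carboxylesterases (Ces) fell in 11 of 13 cases and rose in 1 (median -2.25; camera adjusted p = 0.000133), cytochromes P450 (Cyp) fell in 23 and rose in 1 of 37 (-1.22; adjusted p = 2.3e-05) and Hoxb genes, transcription factors of body axis patterning, fell in 9 of 10 (-1.40; adjusted p = 2.3e-05). Histone genes (Hist) fell in 20 and rose in 1 of 38 (-1.16, adjusted p = 5.98e-05), and collagens (Col) fell in 9 of 23 and rose in 0 (-2.02, adjusted p = 0.00248). Nucleoporins (Nup) rose in 18 of 19 cases (0.66, adjusted p = 2.3e-05) and proteasome subunits Psmd in 10 of 14 (0.59, adjusted p = 0.000324). The stems named were picked from the 21 without a fixed rule, and the others are not reported here. With an estimated correlation none of these stems passed (adjusted p = 0.772).

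Naive replicate 1 held counts of Paneth cell defensins, which belong to the small intestine: 480 of Defa24, 286 of Defa21 and 191 of Defa22, against 34, 14 and 7 in naive replicate 3 and at most 2 in each of the other 7 libraries. These 3 genes were not among those tested. The tested members of the Paneth and small intestinal list had a median of -0.76 in syngeneic against naive libraries, and 0.49 without naive replicate 1. The low-count filter was run anew for the latter, so the members behind these medians may differ.

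Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 5417 genes for allogeneic against syngeneic, and the highest of the others gave 0. The same held for syngeneic against naive (1 gene, highest other 0) and allogeneic against naive (6371 genes, highest other 0). With 10 splits the share is at least 0.1, too few for one under 0.05. Every other split also mixes the groups, which puts the difference between them into the spread. Low counts in those splits are largely built in, so the contrast decides nothing.

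Syngeneic replicate 3 stood apart from syngeneic replicates 1 and 2. Thinning all libraries to the smallest total left its higher correlation with them at 0.973 against 0.987 between those replicates, which argues against depth; leaving out mitochondrially encoded genes gave 0.973 too, but so few genes can hardly move it, so that test decides nothing. Its median position on 400 genes was 0.162 between the naive mean (0) and the mean of syngeneic replicates 1 and 2. Naive libraries left out in turn lay at -0.035 to 0.205, so a naive animal under a syngeneic label could give this position. The genes were chosen on syngeneic replicates 1 and 2, and neither was itself left out and placed. How far below their mean a true syngeneic library would fall is not known, so the position alone does not decide. The position test replaced the first one written for a wrong label, which had gone the other way. In that one B and plasma cell transcripts stood at 2.56 CPM on unscaled totals (2.02 to 3.20), below the 5.61 to 25.9 of naive libraries. That test sets spread between animals against counting noise. T and natural killer cell markers (53.8 CPM against 68.8 to 108.5) and myeloid markers (24.95 against 36.3 to 54.6) also summed below naive libraries. In syngeneic replicates 1 and 2 these sums lay above naive libraries (152.3 and 229, 60.3 and 69.7). Fer1l4 stood at 6.83 CPM beside 7.998 and 7.49 in the other syngeneic libraries. It was named because it passed with replicate 3 counted as syngeneic, so its closeness to them was largely set by that choice and decides nothing. A wrong label and a milder response both stay open, and no biological explanation was tested.

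Mitochondrially encoded transcripts were lower in allogeneic than in syngeneic libraries. A lower share of epithelial cells was tested on 10 pan-epithelial genes, whose median change was 0.25 ± 0.332 (SD), and a lower output of respiratory genes from both genomes on 76 nuclear-encoded subunits, whose median was -0.034 ± 0.234; both argue against these explanations. For uneven carry-over of mitochondrial RNA, shares differed by up to 2.80 times among allogeneic libraries, against 2.66 times between the group means, but this is the group whose change is in question, and naive and syngeneic libraries differed by only 1.67 and 1.56 times. With 3 libraries a group these values leave carry-over open, neither shown nor excluded. The mitochondrial number per cell was not measured, and the donor strain stays open as a biological cause.

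MHC class II transcripts stood 118.9 times higher in allogeneic than in syngeneic libraries as a sum (4079 ± 750 against 34.3 ± 7.61 CPM on unscaled totals). Over 9 pairs of libraries this fold was at least 14.6 times that of B and myeloid cell markers (3.73 overall) and at least 8.01 times that of T and natural killer cell markers (5.73 overall). The B and myeloid sum left out Cd14. As sums, these argue against more antigen-presenting cells at unchanged levels per cell, and against more T cells, as the whole source. The sum does not stand for each marker. Single members of the myeloid list rose by up to 5.65 on the log2 scale (median 0.93), against a class II median of 6.47. A higher class II level per epithelial cell and antigen-presenting cells with more class II per cell both stay open. Neither was tested, since the cells were not separated.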
